A study of Brassica rapa subsp. chinensis with 2 samples.

How the data were processed

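Small RNAs were sequenced on an Illumina Genome Analyzer from total RNA of the above-ground parts of 21-day-old seedlings of a non-heading Chinese cabbage (Brassica rapa, chinensis group). Per the labels, plants grew in 16 h of light and 8 h of dark at 22 °C, and RNA was extracted with TRIzol and treated with DNase. Huaq and Wut, both labelled as wild type, were the 2 genotypes, with 1 library each. Adapter trimming, quality filters, the genome build and the settings of the aligner were not given in the sources used here.

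The deposited library files held raw read counts per distinct sequence, and these counts were used as the authors left them. Each distinct sequence also had at least 1 line in the authors' deposited alignment table, whose layout and name are those of the SOAP aligner. The totals per library were therefore totals of aligned reads, and how many reads failed to align is unknown. The alignment table had 19108447 lines on 24309 reference sequences, named A01 to A10 and scaffolds. All read numbers in that table and in the authors' table of small RNAs within genes equalled those of the library files. Reads of 17 to 24 nt were aligned almost only without a mismatch (0.439% of their reads had 1), while 65.7% of reads of 25 nt or more were aligned with a mismatch. A genotype's variant relative to the reference could thus remove reads of up to 24 nt from these files.

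The authors' deposited microRNA table gave raw read counts of single sequences for 78 entries, with an unscaled Huaq over Wut ratio. The authors' deposited table of matched genes gave 1 Huaq over Wut ratio, or a word for specific to 1 genotype, for 23 genes, and the reads behind each ratio were not stated. The table of small RNAs in genes placed each of 744732 sequences in exactly 1 of 29564 genes, with the authors' word for sense or antisense. Gene identifiers in it carried the prefix Bra; the files pair them with gene names only in the table of matched genes, so at most 2 unnamed genes per direction are given by identifier. The name table of assembly CAAS_Brap_v3.01 held none of these identifiers and was not used.

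Read numbers were expressed as reads per 1000000 aligned reads of the library (RPM). A ratio was always Wut over Huaq, and its 95% interval came from the exact Clopper-Pearson interval of the Wut share of the reads. Shares had exact Clopper-Pearson intervals, and single read numbers exact Poisson intervals. With 1 library per genotype there was no test between genotypes, no p-value and no replicate check. All intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and they compare 2 libraries, not 2 genotypes. Where a library had 0 reads, the ratio was given as a bound against a floor of 3 reads in that library, equal to 0.476 RPM in Huaq and 0.485 in Wut. This bound takes the reads of the other library as fixed and is not a limit at the 95% level, so the lower limit of the exact interval, which is smaller, is given beside it.

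Conserved microRNA families were counted as exact matches to a list of 41 families with fixed mature sequences. Of these, 14 were listed as restricted to Brassicaceae, so conserved here means only that a family was on the list. A family was called at 2-fold or more when it had at least 20 reads over both libraries and an interval leaving out 1. Genes with small RNAs were called at 4-fold or more among those with at least 50 reads over both libraries, by the same rule on the interval. For each of 6 functional lists of families, the median log2 ratio was placed among 10000 random lists of the same size drawn from families of neighbouring abundance rank, as a description of these libraries. Intervals of medians came from 400 Poisson redraws of the reads. In the chromosome shares, the reads of a sequence were divided by its number of listed positions.

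Families named in the text were the 12 most abundant, then up to 8 with the highest and up to 8 with the lowest ratio among those with 20 reads and an interval leaving out 1. From the authors' list, up to 6 of each direction outside the conserved families were named. For genes the rule took the 8 with most reads, the 8 highest and the 8 lowest ratios; these are described as groups because of the identifiers. Lists, rules, comparisons and most alternatives were set before the data were examined. The stretches of rRNA and tRNA and the sequences of opposite arms were written down after the most abundant sequences had been seen. They comprise 5.8S and 5S rRNA, the start of 18S rRNA and a few tRNAs, so their shares are lower limits of all such fragments.

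The counting rule was tested on simulated data for the 3677 genes of the gene comparison, with 200 genes changed. Of 100 genes changed 8-fold, 96% were called, and of 100 changed exactly 4-fold, 50% were called, all in the right direction. None of the unchanged genes was called, and 95.7% of intervals held the true ratio. These draws held counting noise only, so they say nothing about variation between libraries. The random-list step, on simulated reads of 31 families, placed a raised list of 5 members at percentile 99.7 and the same list unraised at 72.9. Both simulated libraries had the same expected reads per family, so a strongly raised list had to stand out. The step was not tested with the wider spread of the real families. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives tried were other denominators, 3' end and mismatch allowances, read minimums, distinct sequences in place of reads, single length classes, single-position sequences, and removal of rRNA and tRNA matches.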

Results

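The data comprised 1 small RNA library of Huaq with 6307078 aligned reads and 1 of Wut with 6187666, from the aerial parts of seedlings. The design compared the small RNA profiles of the 2 genotypes. Huaq had 2109930 distinct sequences, 72.5% of them read once, and Wut had 1737905, 84.4% of them read once. The 10 most abundant sequences took 10.2% of Huaq reads and 9.31% of Wut reads. No value had a replicate, so each difference is one between 2 libraries.

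Both libraries were dominated by 24-nt small RNAs, the class that in plants guides DNA methylation, followed by 21-nt small RNAs, which include most microRNAs. The Wut library held less of both. The share of 24 nt was 46.1% of Huaq reads (exact 95% interval 46.0 to 46.1) and 34.3% of Wut reads (34.3 to 34.4). At 21 nt the shares were 17.3% and 12.4%, and at 22 nt they were 6.72% and 6.77%. Reads of 17 to 20 nt made up 7.92% of Huaq and 13.7% of Wut, and reads of 25 to 36 nt made up 11.1% and 22.7%. Among distinct sequences the 24-nt class differed less, at 57.4% and 53.0%, and so did the 21-nt class, at 6.72% and 6.09%.

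**Figure D1:**
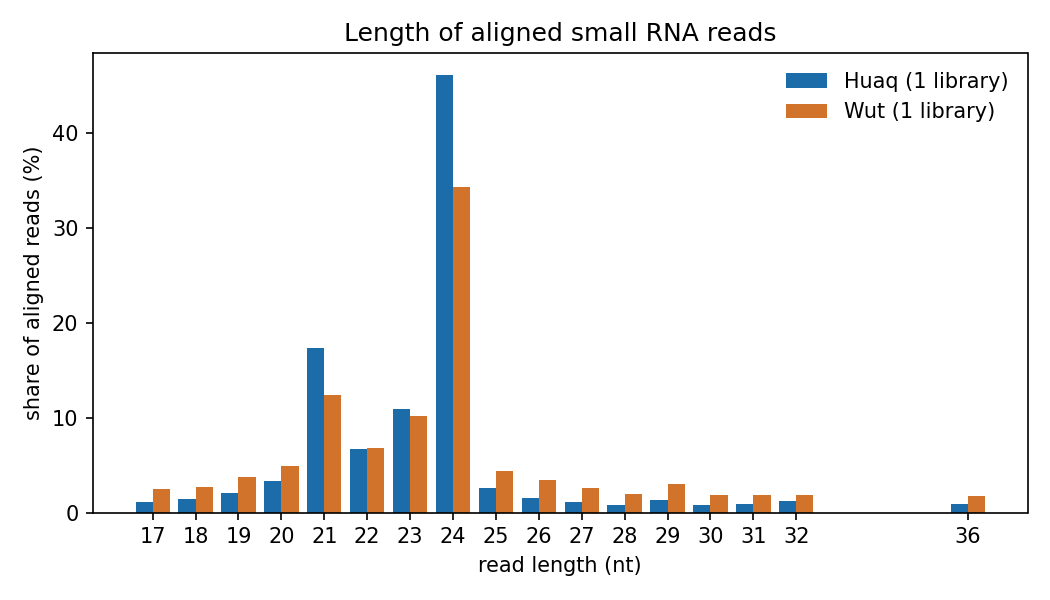
Share of aligned reads in percent (vertical axis) by read length in nt (horizontal axis), 1 bar per library. The 24-nt bar is 46.1% in Huaq and 34.3% in Wut, and Wut bars are higher at every plotted length of 25 nt or more.

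Fragments of ribosomal and transfer RNA were more frequent in the Wut library. Stretches of 5.8S, 18S and 5S rRNA and of a few tRNAs matched 8.79% of Huaq reads and 19.9% of Wut reads. The 5.8S rRNA alone took 3.42% and 8.68%, a ratio of 2.54 (95% interval 2.53 to 2.55). Matches to tRNA took 4.39% and 8.35%. The single exception among these stretches was the plastid tRNA for histidine, at 0.112% in Huaq and 0.0794% in Wut. These shares stand beside every value in reads per 1000000 aligned reads (RPM) below, since they take reads away from other small RNAs.

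Adenine, the usual first base of 24-nt small RNAs, began 56.1% of 24-nt reads in Huaq and 55.0% in Wut. Uracil, the usual first base of microRNAs, began 55.5% and 53.2% of 21-nt reads. Both differences had the opposite sign among distinct sequences. Guanine began more of the Wut reads at both lengths near those of microRNAs, with 11.2% in Huaq and 16.2% in Wut at 21 nt and 17.7% and 25.3% at 22 nt. Adenine began fewer, with 28.1% and 24.1% at 21 nt and 35.8% and 31.2% at 22 nt.

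The libraries shared 497645 distinct sequences, 14.9% of the 3350190 found in either. These shared sequences carried 65.2% of Huaq reads and 76.0% of Wut reads. Among sequences read at least 5 times over both libraries, 81.7% were shared.

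The conserved microRNAs separated the libraries in both directions. Most families had lower RPM in the Wut library, whereas miR403, miR395, miR169, miR156 and the listed miR1885 sequence had more. The families together made up 6.97% of Huaq reads and 4.87% of Wut reads. Of the 41 families on the list, 31 had reads, each at least 20, and their median log2 ratio of Wut over Huaq was -0.94 (interval from redrawn reads -1.11 to -0.85). At 2-fold or more, 3 families were higher and 15 lower in Wut. Scaled to the median family, which moves every log2 ratio by 0.94, the split became 5 higher and 8 lower. Under that scaling 10 families crossed to the other side of 1, namely miR157, miR159, miR162, miR164, miR165, miR391, miR398, miR399, miR400 and miR845.

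**Figure D2:**
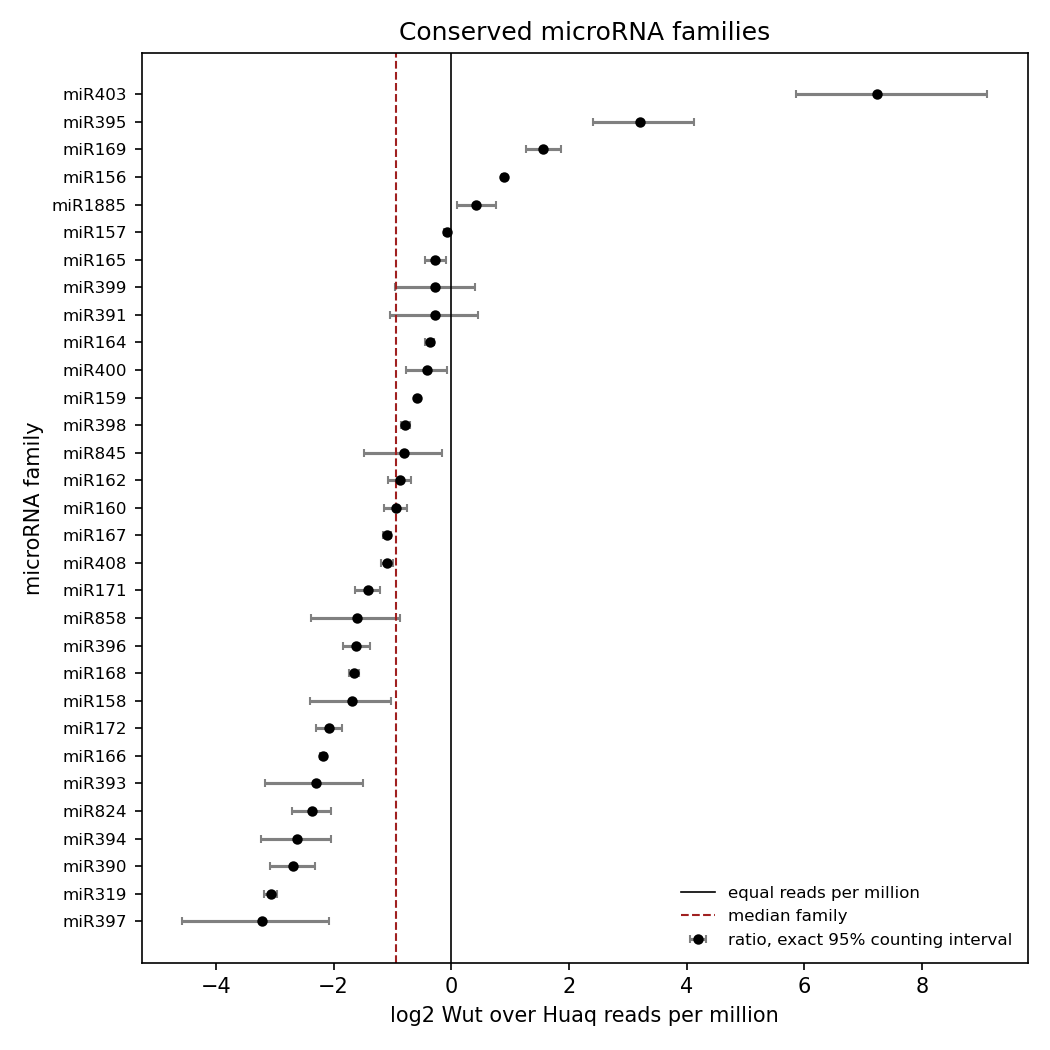
Log2 ratio of Wut over Huaq RPM (horizontal axis) for the 31 conserved microRNA families with reads (vertical axis). Points are ratios of 1 library each with exact 95% counting intervals, the solid line marks equal RPM and the dashed line the median family at -0.94. The 5 families above 0 are miR1885, miR156, miR169, miR395 and miR403, and because the median family lies below 0 they must also lie above it.

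The largest difference was in miR403, which in Arabidopsis targets AGO2, an Argonaute protein of antiviral defence. It had 4 reads in Huaq and 589 in Wut, a ratio of 150.1 (95% interval 58.3 to 553). The sulfate-starvation microRNA miR395 had 14 and 127 reads, a ratio of 9.25 (5.31 to 17.4). With 132 and 383 reads, miR169, which targets NF-YA transcription factors, was 2.96-fold higher (2.42 to 3.63). The juvenile-phase microRNA miR156, which targets SPL transcription factors, was at 3454 RPM in Huaq and 6412 in Wut, a ratio of 1.86 (1.83 to 1.89). The opposite arm of miR156 went the other way, with 169 and 78 reads and a ratio of 0.470 (0.355 to 0.619), as did the bra-MIR156h entry of the authors' deposited table, with 31 and 15 reads and a ratio of 0.493 (0.247 to 0.942). Its near relative miR157 was almost equal, with a ratio of 0.947 (0.913 to 0.982), and it lay above 1 under other scalings. The listed miR1885 sequence, a Brassica microRNA, had a ratio of 1.34 (1.07 to 1.69) from 135 and 178 reads. More abundant miR1885 entries in the authors' deposited table went the other way, with ratios of 0.387 (0.372 to 0.403) for bra-miR1885b.3 from 8497 and 3229 reads and 0.300 (0.273 to 0.329) for bra-miR1885.2 from 2035 and 599.

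Several families of leaf and meristem development were much lower in the Wut library. For miR319, which targets TCP transcription factors, 979 RPM were found in Huaq and 116 in Wut, 8.41-fold fewer (7.79 to 9.10). The leaf-polarity microRNA miR166, which targets class III HD-ZIP genes, was 4.53-fold lower (4.38 to 4.69), while miR165, aimed at the same genes, was 1.21-fold lower (1.07 to 1.36) and lay above 1 relative to the median family. A regulator of AP2-type genes, miR172, was 4.22-fold lower (3.62 to 4.94), and miR394 was 6.12-fold lower (4.12 to 9.40). Laccase-targeting miR397 was lowest in ratio among exact matches, 9.25-fold lower (4.25 to 23.9) from 66 and 7 reads. The trigger of trans-acting small RNAs from TAS3, miR390, was 6.47-fold lower (5.0 to 8.50). Fewer reads in Wut were also found for miR824, 5.16-fold lower (4.13 to 6.51), and miR393, which targets auxin receptors, 4.91-fold lower (2.84 to 8.99). All of these except miR165 lay below the median family, as families named for the 8 lowest ratios must.

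The most abundant family was miR159, which targets MYB genes and held 82.6% of the family reads in Huaq and 79.2% in Wut. It had 57581 RPM in Huaq and 38581 in Wut, a ratio of 0.670 (0.667 to 0.673), and was 1.29 relative to the median family. Close to the median family were miR167, 2.12-fold lower (2.02 to 2.22), and miR408, 2.12-fold lower (1.98 to 2.28). The listed arm of miR408 was its minor arm. The opposite arm held 97.1% of the arm reads in Huaq and 93.5% in Wut, and was 4.92-fold lower in Wut. For miR398, which targets copper superoxide dismutases, the ratio was 0.581 (0.551 to 0.612), and for miR164, which targets NAC genes, it was 0.775 (0.732 to 0.820). The AGO1-targeting miR168 was 3.14-fold lower (2.95 to 3.35).

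By function, 12 of the 13 development families were below 1, as were 26 of the 31 families in all. Relative to the median family, 5 of the 13 lay above and 7 below. Their median log2 ratio of -1.08 stood at percentile 31.9 of random lists. The 4 auxin-related families were all below 1, among them miR167 and miR160, with a median of -1.69 at percentile 16.3. Of the 6 measured nutrient families, miR169 and miR395 were above 1 and miR398, miR408, miR399 and miR397 below, with a median of -0.53 at percentile 84.3. The interval of miR399 included 1, with 43 and 35 reads and a ratio of 0.830 (0.515 to 1.33). In the authors' deposited table bra-MIR399a went the other way, with 11 and 38 reads, a ratio of 3.52 (1.76 to 7.64). Relative to the median family this list lay above 0, at 0.41. In the copper list, miR398, miR408 and miR397 were all below 1, with a median of -1.09 at percentile 36.7. The list of small RNA machinery had miR403 above 1 and miR168, miR162 and miR390 below, with a median of -1.27 at percentile 36.7. Among 14 Brassicaceae families 6 were measured, including miR824, miR1885 and miR400, with a median of -0.61 at percentile 69.8. Its miR158 was 3.22-fold lower from 82 and 25 reads, while in the authors' deposited table the more abundant bra-MIR158a entry, with 637 and 876 reads, had a ratio of 1.40 (1.26 to 1.55). None of these lists lay outside the central 95% of its random lists.

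The tasiARF small RNA, which is made from TAS3 and targets auxin response factors, had 10 reads in Huaq and 3 in Wut. The ratio of 0.306 had an interval from 0.0541 to 1.19, so a difference was not detectable at this depth.

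The authors' deposited microRNA table listed 78 entries, 57 of them in the conserved families above and 21 outside. Of the 66 entries with at least 20 reads, 11 were higher in Wut at 2-fold or more and 33 lower, with a median log2 ratio of -1.0. Outside the conserved families, 6 were higher and 9 lower. Among these, bra-miR5711 had 0 reads in Huaq and 154 in Wut, at least 52.3-fold higher against the floor (exact 95% limit 42.0). With 32 and 600 reads, bra-miR5718 was 19.1-fold higher (13.4 to 28.2). Smaller ratios above 1 were found for bra-miR5714 at 6.12 (2.35 to 20.2), bra-miR5716 at 4.93 (2.94 to 8.70), bra-miR5725 at 2.95 (2.02 to 4.39) and bra-miR5720 at 2.64 (1.48 to 4.93). In the other direction, bra-miR5726 was 10.5-fold lower (4.86 to 27.0), bra-MIR472 was 5.89-fold lower (2.02 to 23.3) and bra-miR5721 was 5.30-fold lower (2.01 to 17.6). The entry bra-miR5713 with 226 and 46 reads was 4.82-fold lower (3.50 to 6.77), bra-miR5719 was 3.04-fold lower (1.81 to 5.32) and bra-miR5724 was 2.31-fold lower (1.65 to 3.27).

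Small RNAs inside annotated genes differed for many genes, and fewer of these were higher than lower in Wut. Gene-derived sequences held 22.5% of Huaq reads and 24.3% of Wut reads. Of 3677 genes with at least 50 reads, 189 were higher in Wut at 4-fold or more and 362 lower, while 60.6% of genes lay within 2-fold. The median log2 ratio was -0.44, and scaled to the median gene the split was 291 higher and 284 lower. The 8 genes with most reads held 31.7% of gene-derived reads. In 6 of them more than 50% of reads matched rRNA or tRNA, 1 held the miR156 sequence, and 1 held 22-nt-led small RNAs of both strands, 2.10-fold lower in Wut (2.06 to 2.14).

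The extremes were genes read in 1 library alone. The 8 highest ratios all had 0 Huaq reads, and the 8 lowest all had 0 Wut reads. Bra016188, at 18987273 to 18989803 on A07 (positions as in the files, on a build not given in the sources used here), had 1251 Wut reads, led by 21 nt with 75.8%, and was at least 425-fold higher against the floor (exact 95% limit 345). Only 19.3% of its reads had a single genome position, so most of them also align elsewhere. Bra002378, at 9955383 to 9958402 on A10, had 200 Wut reads, 79.5% of them 24 nt, and was at least 68.0-fold higher (limit 54.8). Bra023647, at 4367599 to 4370487 on A02, had 436 Huaq reads, 75.0% of 21 nt, and was at least 142.6-fold lower (limit 115.5). Bra004739, at 1587342 to 1589335 on A05, had 307 Huaq reads, 82.1% of 24 nt, and was at least 100.4-fold lower (limit 81.2). Across the 16 genes, 4 were led by 21-nt and 12 by 24-nt reads, and the smallest bounds were 28.2-fold higher (limit 22.4) and 35.97-fold lower (limit 28.8). Another of the 8 lowest genes lay near Bra023647, at 4383977 to 4384702 on A02, so the 16 genes need not be separate loci. The files do not pair these identifiers with gene names.

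By size, 24-nt reads made up 48.3% of gene-derived reads in Huaq and 35.0% in Wut, and 21-nt reads 11.3% and 8.46%. Antisense reads were 47.4% in Huaq and 51.7% in Wut. This order came from the gene with most reads, in which 99.1% of reads were antisense and 51.1% matched rRNA or tRNA. Without that gene the antisense shares were 43.1% and 38.8%.

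Among the 23 genes of the authors' table of matched genes, which pairs Bra identifiers with Arabidopsis names, most had mainly antisense small RNAs (21 of 23). The cation exchanger gene CHX4, called specific to Wut in the authors' deposited table, had 13 reads in Huaq and 391 in Wut over the whole gene, 30.7-fold higher. For CTR1, a kinase of ethylene signalling called specific to Huaq there, the gene had 3416 and 886 reads, a ratio of 0.264, so small RNAs were present in both libraries. The bZIP factor gene AREB3, also called specific to Huaq, had 172 and 5 reads, a ratio of 0.0296. The reads behind these 3 words were not traced, so the words may describe single sequences and not whole genes. Over whole genes, AT3G59760, an O-acetylserine lyase gene, had 10 and 77 reads and a ratio of 7.85, and the vascular NAC gene ANAC030 had 393 and 120 reads and a ratio of 0.311. The GRAS genes HAM1 and HAM3, targets of miR171, had ratios of 0.449 (0.385 to 0.524) and 0.735 (0.521 to 1.03). Most reads of HAM1, 476 of 549 in Huaq and 195 of 242 in Wut, were the miR171 sequence itself.

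Along the genome, chromosome A06 carried 16.0% of Huaq and 22.7% of Wut reads after division by positions, and unplaced sequences carried 13.6% and 18.9%. With 1-position sequences alone, A06 was at 10.9% and 9.22%, and unplaced sequences stayed higher in Wut at 8.90% and 12.6%. A02 had 10.5% of Huaq and 7.54% of Wut reads, or 10.5% and 9.76% with 1-position sequences.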

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

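The sequences of opposite arms, the test for a missing miR403 locus, the reads per base of its opposite arm and the test of reads at a single genome position were chosen only after the results had been seen. The predictions of the other tests were written before their results. The opposite arms of microRNA precursors, those other than the listed mature arm, entered no planned comparison. Their reads were far over the limit of 0 counts. The opposite arm of miR408 had 99883 reads over both libraries, 83277 in Huaq and 16606 in Wut, and was 97.1% of the arm reads in Huaq and 93.5% in Wut. It was 4.92-fold lower in Wut, against 2.12-fold for the mature arm. The opposite arm of miR166 had 25142 reads and was 3.46-fold lower in Wut. That of miR396 had 16827 reads, 95.1% of the arm reads in Huaq and 95.8% in Wut, and was 2.60-fold lower.

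The shift of most families to lower RPM in the Wut library was weighed against 3 technical explanations, each of which predicted a median log2 ratio near 0 once removed. After removal of rRNA and tRNA matches the median family was at -0.75. Relative to reads of 20 to 24 nt it was at -0.64, and with 3' ends allowed to vary by up to 2 nt it was at -0.89. The tables argue against 3' ends of that range as the whole cause. The first 2 settings reduced the shift from -0.94 but cannot decide. The first removed only the listed stretches, a lower limit of all rRNA and tRNA fragments. The second still counted such fragments, among them a 24-nt 5.8S rRNA sequence with 10401 reads in Huaq and 31587 in Wut. A difference in library preparation or in RNA quality that acts on microRNAs themselves, and a difference between the genotypes, stay open and were not tested, since each genotype had 1 library.

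For miR403, a variant in the mature Huaq sequence that only kept reads from aligning would leave the opposite arm alike in both libraries. But that arm had 1 read in Huaq and 27 in Wut, a log2 ratio of 4.78 (interval of the ratio 4.54 to 1127). A variant in the mature sequence that also lowered the output of both arms is not covered by this comparison and stays open. No Huaq sequence within 1 mismatch added to the 4 reads, though such reads of up to 24 nt were seldom aligned. A missing locus is argued against by 115 Huaq reads of 23 or 24 nt that begin between the arms and align exactly and nowhere else, at 266455 to 266510 on A05. Of these, 89 lay on the plus and 26 on the minus strand, and 47 reached into the opposite arm. Wut had 0 such reads, at least 37.6-fold fewer against the floor (exact 95% limit 30.1). Variants of Wut between the arms could also remove reads of this length from the files, and this was not tested. A genotype difference at the locus, with 24-nt small RNAs of both strands in Huaq and the microRNA in Wut, may be followed up as a hypothesis. Variants in both arms of Huaq stay open. Over the opposite arm, at 266490 to 266511, exact Huaq reads with 1 position numbered 12 or more per base up to 266498, which argues against a variant there, but 6 or fewer per base after it.

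The 16 named genes with small RNAs of 1 library alone were weighed against reads shared with other positions. Of them, 11 had over 50% of their reads at a single genome position, while Bra016188, with the largest bound, had 19.3%. The planned comparisons of these genes, a median absolute log2 ratio of 8.15 with single-position sequences and of 6.53 with reads of other lengths than the leading one, could not have come out otherwise, because any part of 0 reads is 0. Loci that are missing, or too different from the reference to align, and loci that are present but give no small RNAs therefore cannot be told apart here.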

How the results depend on the processing

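No paired analysis was possible because each genotype had 1 library. Alternatives added after seeing the data were removal of rRNA and tRNA matches, removal of the gene with most reads, 1-position sequences for genes, reads of 20 to 24 nt as denominator, scaling to the median gene, and median scaling for the number of families at 2-fold. Restricting lengths to aligned reads, and genes to sequences listed in 1 gene, changed nothing by construction, as all reads were of that kind. The causes of changes below were not tested unless the setting itself shows them.

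The lower 24-nt share in Wut, -11.8 percentage points, stayed negative in each setting: -4.38 for distinct sequences, -14.6 for sequences read at least 2 times and -9.44 without rRNA and tRNA. The 5' adenine difference of -1.05 points became 1.32 for distinct sequences and -1.47 without the 10 most abundant sequences, and that of 21-nt uracil, -2.24, became 2.49 for distinct sequences. Shared sequences went from 14.9% to 81.7% with at least 5 reads. The antisense difference of 4.27 points became 1.72 without rRNA and tRNA and -4.22 without the gene with most reads. The unplaced excess of 5.24 points became 3.72 for 1-position and 1.17 for distinct sequences.

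The median family log2 ratio of -0.94 was -0.42 relative to family reads, 0 by construction under median scaling, -0.75 relative to reads of 20 to 22 nt, -0.52 relative to reads of 24 nt, -0.75 without rRNA and tRNA and -0.64 relative to reads of 20 to 24 nt. The number of families at 2-fold, 18, ranged from 13 to 18 over the settings run, and tasiARF, at -1.71, was at -1.29 with 3' ends up to 2 nt different. Single families turned as follows. For miR157 the log2 ratio was 0.44, 0.86, 0.12, 0.35, 0.11 and 0.22 relative to family reads, under median scaling, and relative to reads of 20 to 22 nt, of 24 nt, without rRNA and tRNA, and of 20 to 24 nt. Relative to family reads, under median scaling and relative to reads of 24 nt, miR164 was 0.15, 0.57 and 0.058 and miR165 was 0.25, 0.67 and 0.16, with 0.033 for miR165 relative to reads of 20 to 24 nt. With 3' ends up to 2 nt different miR397 went from -3.21 to -2.51 and was no longer lowest, behind miR319 at -2.95, miR390 at -2.66 and miR394 at -2.57. With 1 mismatch allowed miR169 went from 1.56 to 2.37. Under median scaling miR159 was 0.36 and miR398 was 0.16.

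Median scaling put the list medians at -0.14 (development), -0.75 (auxin), 0.41 (nutrient), -0.32 (machinery), 0.33 (Brassicaceae) and -0.15 (copper). With at least 100 reads, auxin was at -1.08, nutrient 0.39, Brassicaceae -1.05 and copper -0.94. The authors' list moved from -1.0 to -0.48 relative to family reads.

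The 551 genes at 4-fold were 174 with a minimum of 200 reads and 89 with 21-nt reads, where fewer genes could be tested, and 351 for distinct sequences, with 188 higher and 163 lower. Other settings gave 372 to 575, and none called a gene in the opposite direction. Families with few reads, such as miR397 and miR393, have wide intervals.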

Other observations

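The tests on the miR1885 precursor were chosen only after the result was seen, and the prediction for both arms was written before. Single abundant sequences read almost in 1 library alone were few. Of 555 sequences with at least 1000 reads, 3 were at least 32-fold higher and 9 at least 32-fold lower in Wut. One was TGGCTCTGATACCATGAAGTA, with 0 reads in Huaq and 1664 in Wut, at 1 position in a gene on A05. In the other direction and also at 1 position each, TTGACAGAAGAGAGCGAGCAC had 1844 and 1 reads, and AATAAAGCTGTGGGAAGATAC had 2126 and 35. Without its first base, the former differs by 1 base from the listed miR156 sequence. The latter, on A09, begins with the last bases of a more abundant 21-nt sequence. That sequence had 10667 reads in Huaq and 4312 in Wut, only 2.43-fold lower (2.34 to 2.51). Whether it comes from the same position on A09 was not tested, so the reads of the latter alone do not show a silent locus in Wut. Several of the 9 lower sequences overlap one another, in the miR1885 precursor on A06 and on A09, so they are not 9 separate loci.

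The strongest of these lay in the precursor of miR1885 on A06. Products beginning at position 25285134, such as TTTGAATGTGACTAAGAAAGC, had 11334 reads of up to 24 nt in Huaq and 1 in Wut. Products of the 3' part, from 25285178 on, had 20512 and 8307 reads, 2.42-fold lower in Wut (2.36 to 2.49), and the listed miR1885 sequence was 1.34-fold higher. A candidate explanation is a Wut variant that keeps reads of up to 24 nt over it from aligning, since these were aligned almost only without a mismatch. Counted from 1 at position 25285134, the substitution G4C was found in 44 of 44 Wut reads of 25 nt or more over that base, 100% (exact 95% interval 92.0 to 100), and in 3 of 46 Huaq reads, 6.52% (1.37 to 17.9). Reads of up to 24 nt over the base numbered 19561 in Huaq and 5 in Wut, so this difference may be one of alignment rather than of abundance.

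The base was not picked by the rule written first. That rule took the base with most other-base reads over both libraries, which was A30T, with the other base in 171 of 443 Huaq reads (38.6%) and 1 of 51 Wut reads, and by it the variant explanation failed. The rule was changed, after both bases had been seen, to the base with the highest Wut share among bases with at least 10 such reads, since a variant of Wut must show in Wut reads. The result for G4C therefore rests on a choice made with the data in view and has not been tested in other Wut reads.

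Products that begin just past that base do not contain it, so loss through G4C cannot lower them. They had 18468 reads in Huaq and 98 in Wut, a log2 ratio that lay -6.25 from that of the 3' part. Products that begin at 25285140 went the other way, with 85 and 479 reads, 5.74-fold higher (4.55 to 7.32), but their neighbours did not. Products from 25285139 had 472 and 47 reads, 9.85-fold lower, and products from 25285141 had 1447 and 215, 6.60-fold lower. The tables argue against a single further Wut variant that keeps these products from aligning. Wut reads of 25 nt or more that begin past G4C can carry 1 mismatch of their own, and another base was found in 0 of 9 at 25285138 and 0 of 10 at 25285139. The highest upper 95% limit at any base through 25285161 was 33.6%. The 479 Wut reads from 25285140 also align, 393 of them as TGTGACTAAGAAAGCCTCTACG, without a mismatch. Molecules with 2 or more further differences would still be absent from the files, and what else lowered these products was not tested. The same kind of loss can touch any other sequence read in 1 library alone, and was not tested there.

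A hypothesis that differences arise before the arms of a precursor separate predicted that both arms share their sign. In 13 families with at least 20 reads of each listed arm, 92.3% shared it, and miR156 alone did not. Because 12 of the opposite arms and 11 of the mature arms were below 1, chance alone would give 79.3%, and relative to the median of its own kind only 53.8% of families had both arms on the same side, so this does not decide the question. The listed opposite arm of miR403 had no reads, but that of its locus had, and with it 14 families gave 92.9%, against 70.4% from chance and 57.1% on the same side.

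The authors' deposited ratios for matched genes were traced to reads. All 20 numbers in that table equalled, within a relative difference of 1e-06, the unscaled Huaq over Wut ratio of exactly 1 distinct sequence aligned in the gene, not of the gene's reads. In 10 genes that sequence was listed under another gene, where it also aligns. HAM1 and HAM3 both had 2.44, the ratio of the miR171 sequence with 476 and 195 reads. For ATG6 the deposited 0.463 was the ratio of a 30-nt tRNA fragment with 16432 and 35516 reads. In 4 of the 20 genes, the reads of the whole gene lay on the other side of 1. For CAP-E1, HTR11 and APR the interval of the Wut over Huaq ratio included 1, at 0.875 to 19.2, 0.543 to 2.48 and 0.890 to 1.68. For NTH2 it left out 1, with a ratio of 0.734 (0.558 to 0.962).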
